A study of Mus musculus with 12 samples.

How the data were processed

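Gene expression was measured in total RNA of immortalized mouse embryonic fibroblasts (MEFs), connective tissue cells grown from embryos, that carry both copies of Rictor (Rictor+/+) or none (Rictor-/-). Each line was left untreated or received mouse interferon-alpha (IFN-alpha) at 2500 U/ml, with RNA taken 24 hours later. The RNA was labelled with biotin and hybridized to Illumina mouse BeadChip arrays, on which each probe is a short oligonucleotide carried by many beads. There were 12 arrays in 4 groups of 3. The labels do not say whether the 3 arrays of a group came from separate cultures, so every p-value here measures only the spread between these arrays. Each genotype is a single cell line as far as the labels tell, so genotype and line coincide. The label field on treatment names small interfering RNAs against Rictor for every sample, which is at odds with the knockout genotype in the other fields; the genotype fields were followed.

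The deposited non-normalized table gives intensity, the average bead signal of each of 45281 probes on each array, on a linear scale and without background subtraction. Per the labels the authors used BeadStudio, of which no version is stated. The second deposited table holds log2 values of 17003 probes, normalized between arrays by a method that the authors do not state. On each array its values followed the rank of that array's own intensities, with Spearman correlations across probes of 0.9978 to 0.99993. The rule by which its probes were selected is not stated. Among probes with a mean log2 signal of at least 9, the 7147 in the table had a median SD of 0.41 across arrays and the 1561 outside it a median SD of 0.21. Gene names were available only for probes in this table, of which 14461 named 1 gene, 5 several genes and 2542 none. The counts of named genes below may therefore be weighted towards genes that vary.

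The intensities were processed with R 4.3.3 and limma 3.58.1. The plan fixed before the data were examined relied on detection p-values or control probes, which the non-normalized table does not hold, so a substitute was chosen after the table was seen. The background of each array was taken as the mode of its signals, with an SD from the signals below the mode. The normal-exponential (normexp) correction was applied with these values and an offset of 16, followed by quantile normalization and log2. Quantile normalization gives all arrays the same distribution, so a general shift in expression cannot appear. A probe counted as above background on an array when its upper-tail probability under the background was below 0.01, and 20856 probes above background on at least 3 of the 12 arrays were kept. Of these, 11870 named 1 gene and 8986 named none. Where several kept probes named a gene, the brightest by its mean over all arrays stood for it. This left 17259 features, 8273 of them named genes. Where a group lay below background on all 3 of its arrays, a fold difference is given only as a lower bound, computed against the background limit. A fold against a group above background on 1 or 2 of its 3 arrays is given as fitted and depends in part on the background.

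The background mode was 210.8 to 240.5 on 6 arrays and 107.6 to 127.9 on the other 6. Each of these sets of arrays held all 4 groups, but unevenly. The set of high background held arrays 1, 2, 5 and 6 of Rictor+/+ and arrays 3 and 4 of Rictor-/- cells. The set of low background held arrays 9 and 10 of Rictor+/+ and arrays 7, 8, 11 and 12 of Rictor-/- cells. Background level and genotype therefore coincide in part. The labels name no batch. The sets were defined from the signals, and each comparison was also run within each set and with the set as a block. Genes called on all 12 arrays tend to keep their direction within a set, because both sets entered the call. The total signal was 39160400 to 62338100 on 11 arrays. It was 21292300 on array 12, an IFN-treated Rictor-/- array, with 31.5% of probes above background against 34.1% to 46.9% on the others. For arrays the number of replicates limits the precision; the median SE of a log2 change was 0.29 for a comparison of 2 groups and 0.40 for a difference of responses.

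A limma model with a mean per group was fitted to all 12 arrays, with 8 residual degrees of freedom and 4.51 added by empirical Bayes moderation. The 5 comparisons were IFN-treated against untreated in each genotype, the difference of these responses (Rictor-/- minus Rictor+/+), and Rictor-/- against Rictor+/+ without and with IFN-alpha. All tests were two-sided. P-values were adjusted by Benjamini-Hochberg over the 17259 features of a comparison, and a gene was called at an adjusted p under 0.05. The 33 gene lists were fixed before the data were examined. They cover interferon responses, growth, metabolism, stress, matrix, position in the body and markers of other cell types. They were tested with camera in limma, a two-sided test of whether a list ranks differently from the other named genes, with the preset inter-gene correlation of 0.01 and again with the correlation estimated per list, adjusted over the 32 lists that had at least 3 measured members. Counts of list members were also adjusted over the list alone. Genes named in the text follow a rule written beforehand, namely the 10 largest changes per direction among called genes whose arrays do not overlap between groups, up to 4 members of each list with the smallest adjusted p, and a fixed set of interferon and Rictor genes. For the difference of responses the rule on overlap was not applied. Exceptions are marked in the text.

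The limma fit was tested on simulated log2 values with independent noise and 50 features per size of change. Background correction, normalization, the filter and the choice of probes were not simulated. Residuals of the real arrays were correlated, by up to 0.54 between arrays of different groups. The highest values were 0.54 for arrays 10 and 12, 0.491 for arrays 1 and 10 and 0.437 for arrays 1 and 12. Arrays 1, 10 and 12 also had the lowest array weights, at 0.349, 0.396 and 0.248. The simulated rates may therefore not hold for the real arrays. At 2-fold, 4-fold and 8-fold, 32%, 86% and 98% were called for the response of Rictor+/+ cells and 2%, 48% and 84% for the difference of responses. Between 0.943% and 9.84% of the simulated calls were false. The alternatives tried were no background correction, cyclic loess and median scaling, 3 other filters on dim probes, the deposited values, another variance model, only the compared groups, array weights, a block on the title numbers, the mean of a gene's probes, and leaving out each array. Another background estimate, an offset of 50, the background sets, leaving out 3 arrays together, list medians without each array and adjusting over named genes only were added after the data had been seen. A block on the BeadChip had been planned, but no chip was given for the arrays. Symbols were checked by Entrez identifier against a RefSeq gene table of assembly GRCm38.p6, which was used for names only. No genome positions are given because the files name no genome build. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.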

Results

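Rictor is the defining subunit of mTOR complex 2, a kinase complex that acts on Akt, SGK and other kinases. The study asks what Rictor complexes contribute to the transcription that type I interferon starts and to its restraint of growth. The data were probe intensities from 12 Illumina mouse BeadChip arrays of immortalized Rictor+/+ and Rictor-/- mouse embryonic fibroblasts (MEFs), with 3 arrays each of untreated Rictor+/+, IFN-treated Rictor+/+, untreated Rictor-/- and IFN-treated Rictor-/- cells. IFN-alpha was given at 2500 U/ml and RNA was taken after 24 hours. The total signal per array was 39160400 to 62338100, apart from array 12, an IFN-treated Rictor-/- array with 21292300. Changes below are log2 differences of normalized intensity ± SE from the limma model, with n = 3 arrays per group, and adjusted p-values are those of limma.

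The Rictor probe was close to background in both lines and did not differ between them. Its mean log2 intensity was 6.30 ± 0.85 (SD, n = 3) in untreated Rictor+/+ and 6.55 ± 0.39 in untreated Rictor-/- cells, a log2 difference of 0.26 ± 0.49 with a limma adjusted p of 0.796. With IFN-alpha the means were 6.34 ± 0.48 and 6.07 ± 0.93. It was above background on 2, 2, 2 and 1 of 3 arrays in the groups as listed above. The position of the probe relative to the deleted part of the gene is not known, so this signal checks nothing about the knockout. The lines themselves were clearly separate on the arrays, since the first principal component, with 48.8% of the variance, placed all Rictor+/+ arrays on one side and all Rictor-/- arrays on the other. Xist, the RNA that silences an X chromosome in female cells, was above background on 0 of 6 Rictor+/+ and 6 of 6 Rictor-/- arrays. The Y-linked gene Eif2s3y was above background on 6 of 6 and 0 of 6, and Kdm5d, also Y-linked, on 3 of 6 and 0 of 6.

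The first comparison asks which genes IFN-alpha changed in Rictor+/+ cells. It raised 294 named genes and lowered 42, of which 280 and 33 changed at least 2-fold. The lowered genes numbered 6 with median scaling and 70 with no background correction, and array weights gave 481 raised and 280 lowered. Among the largest rises was that of Usp18, a protease that removes ISG15 from proteins and dampens interferon signalling, whose signal was 299.8-fold higher (log2 change 8.23 ± 0.37, limma adjusted p = 3.05e-08). Oas1g, a member of the 2'-5'-oligoadenylate synthetase family that activates RNase L against viral RNA, rose by 7.98 ± 0.22 on the log2 scale (253-fold). Oas2 and Mx1, an antiviral GTPase, were below background before treatment and rose at least 70.8-fold and at least 48.0-fold. The chemokine Cxcl10 rose 91.1-fold. Decreases were smaller. The prolyl hydroxylase gene Egln3 fell by 1.79 ± 0.30 on the log2 scale (3.46-fold, adjusted p = 0.0041) and Tagln, which encodes the actin-binding protein transgelin, fell 2.90-fold.

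Of the 35 measured antiviral effectors, 30 rose, 0 fell and 5 were not called in Rictor+/+ cells, with 32 raised when adjusted over the list alone. Rsad2 (viperin) rose 81.0-fold, Mx2 80.9-fold and Cmpk2 56.8-fold, and Isg15, a ubiquitin-like modifier, rose 32.3-fold. The median log2 change was 4.11 (camera adjusted p = 2.19e-79, 6.14e-04 with an estimated correlation). In this list 8 members were below background on all untreated arrays, so that their changes, and the median, are compressed by the background. Among 16 genes of interferon signalling and its feedback 6 rose and 10 were not called, with 6 raised and 1 lowered when adjusted over the list alone (camera adjusted p = 1.38e-06). The transcription factor genes Irf7, Stat2 and Irf9 rose at least 37.7-fold, 9.88-fold and 6.23-fold, and the feedback inhibitor Socs1 rose 6.36-fold. The receptor chain Ifnar2 had a log2 change of -0.36 ± 0.27, which was not called. Of 21 genes of major histocompatibility complex (MHC) class I antigen presentation 17 rose, or 19 when adjusted over the list alone, and 0 fell (camera adjusted p = 2.17e-38). The immunoproteasome subunits Psmb9 and Psmb8 rose 81.8-fold and 57.6-fold, and the peptide transporter subunit Tap1 rose at least 20.1-fold. All 11 interferon-induced GTPases rose, such as Gbp3 (48.4-fold) and Irgm2 (38.2-fold), with a camera adjusted p of 6.10e-29.

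Of 16 nucleic acid sensors 11 rose in Rictor+/+ cells, or 12 when adjusted over the list alone, and 0 fell (camera adjusted p = 1.83e-24). They included Ifi205 (106-fold), Dhx58 (38.5-fold) and the double-stranded RNA sensors Ifih1 (10.7-fold) and Tlr3 (at least 6.28-fold). Of 16 Schlafen and growth-restraining genes 6 rose, or 7 when adjusted over the list alone, among them Slfn2 (at least 7.68-fold), Daxx (7.42-fold) and the inflammatory caspase Casp4 (5.96-fold), with a camera adjusted p of 1.88e-08. Of 13 chemokines and cytokines 9 rose, also when adjusted over the list alone, such as Cxcl11 (at least 6.66-fold), Il15 (9.26-fold) and Il6 (5.10-fold), with a camera adjusted p of 1.07e-17. Of the genes above, Oas1g, Mx2, Socs1, Psmb9, Ifi205, Ifih1, Il15 and Il6 were above background on 1 of 3 untreated Rictor+/+ arrays, so the background shapes their folds in part. These 7 lists kept their calls with an estimated correlation, where their adjusted p ranged from 3.31e-04 to 0.00658.

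Other lists ranked low in IFN-treated Rictor+/+ cells although few of their members were called. For mitosis and G2/M genes the median log2 change was -0.56 and 0 of 24 members were called (camera adjusted p = 3.64e-06; adjusted p = 0.438 with an estimated correlation). For DNA replication genes it was -0.39 with 0 of 27 called (0.016; 0.661 with an estimated correlation). Cholesterol synthesis had a median of -0.40 with 0 of 16 called and 2 lowered when adjusted over the list alone (0.000356; 0.311 with an estimated correlation). Fatty acid synthesis had -0.38 with 0 of 8 called (0.033; 0.426 with an estimated correlation). Contractile and serum response factor genes had -0.32 with Tagln as the single call of 23 (0.012; 0.179 with an estimated correlation), and the respiratory chain had -0.22 with 1 of 23 lowered, or 2 when adjusted over the list alone (0.012; 0.368 with an estimated correlation). None of these 6 lists held its call with an estimated correlation. The DNA replication median was -0.253 without array 2, the contractile median -0.0938 without array 1, and in the arrays of low background the mitosis and contractile medians were -0.243 and -0.0704 and the respiratory median -0.383. The remaining 19 tested lists were not called, with adjusted p from 0.119 to 0.993; the median, mean and test differed in sign for the NRF2, Hox and limb, endothelial and adipocyte lists. Within the 6 arrays of high and the 6 of low background all 336 called genes kept their direction. The calls came from these same arrays, so this is no independent check. The counts were 199 raised and 5 lowered in the former and 78 and 1 in the latter, and these fits hold 1 or 2 arrays per group, so that a lone array is assumed to vary like the other groups; without array 2, 5, 6 or 9 the lowered genes numbered 19, 20, 27 and 26, and with array weights 280, which made 63.2% of the calls rises against 87.5%.

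The same comparison in Rictor-/- cells gave 106 raised and 4 lowered named genes, of which 105 and 3 changed at least 2-fold. With array weights the counts were 163 raised and 15 lowered. Usp18 was again among the largest rises, with 192-fold (log2 change 7.58 ± 0.37, limma adjusted p = 1.14e-07), together with Oasl2 (159.5-fold), Isg15 (87.1-fold) and Rsad2 (at least 41.7-fold). Irf7 rose at least 19.1-fold, Irf9 6.41-fold and Stat2 5.82-fold, and Cxcl10 at least 19.1-fold. Ifit2, an antiviral RNA-binding protein gene, had a log2 change of 0.88 ± 0.30 that was not called (adjusted p = 0.563), and Slfn2 was below background with and without IFN-alpha. Socs1 had a log2 change of 0.67 ± 0.43 (adjusted p = 0.812). The 4 lowered genes were Fggy (2.72-fold), Tbc1d12, Ptprz1 and Kctd12b.

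Most antiviral effectors rose here too, with 26 of 35 raised and 9 not called in Rictor-/- cells, or 29 raised when adjusted over the list alone. Their median log2 change was 3.09 (camera adjusted p = 2.37e-84). Examples were Ifit3 (61.8-fold) and Mx2 (at least 22.1-fold). Of the interferon signalling genes 4 of 16 rose, with 4 raised and 1 lowered when adjusted over the list alone (4.40e-07). Of the MHC class I genes 12 of 21 rose, or 18 when adjusted over the list alone (8.52e-38), with Psmb8 19.2-fold and Psmb9, above background on 1 of 3 untreated arrays, 8.99-fold higher. Of the GTPases 8 of 11 rose, or 10 when adjusted over the list alone (2.71e-29), with Gbp3 63.5-fold and Irgm2 27.7-fold higher. Of the nucleic acid sensors 8 of 16 rose, or 11 when adjusted over the list alone (1.69e-21), with Ddx58, which encodes RIG-I, 11.6-fold higher. Of the chemokines and cytokines 3 of 13 rose, or 4 when adjusted over the list alone (2.99e-06), namely Cxcl10, Il15 (2.96-fold) and Il7 (2.43-fold). These 6 lists kept their calls with an estimated correlation, at adjusted p from 3.91e-04 to 0.0162. Among Schlafen and growth-restraining genes only Daxx was called (2.75-fold), or 3 genes when adjusted over the list alone, and the list as a whole was not (0.136).

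In Rictor-/- cells DNA replication genes ranked high with a median log2 change of 0.41 (camera adjusted p = 0.000102; adjusted p = 0.468 with an estimated correlation), and so did mitosis genes at 0.30 (0.000905; 0.534 with an estimated correlation) and ATF4 and endoplasmic reticulum stress genes at 0.30 (0.00217; 0.247 with an estimated correlation). Contractile genes ranked low at -0.29 (0.0421; 0.279 with an estimated correlation). As values, these medians depended on few arrays and on the scaling. With median scaling the median of all features was -0.263 against -0.0383, so list medians under that setting include a general shift. They do not by themselves show that a list moved relative to other genes. For DNA replication the median was 0.102 without array 3, 0.0633 with median scaling, and 0.91 and 0.0803 in the arrays of high and low background. For mitosis it was 0.0431 without array 3, 0.201 without array 12, 0.0741 with median scaling, and 0.791 and 0.0925 in the sets. For ATF4 genes it was 0.0186 with median scaling and 0.197 in the arrays of high background, and for contractile genes -0.51 with median scaling and -0.147 with cyclic loess. No member of these 4 lists was called by limma, over all genes or when adjusted over the list alone. The other 22 tested lists, the Schlafen list among them, were not called, with adjusted p from 0.111 to 0.997; the median, mean and test differed in sign for the NF-kB, TGF-beta, sex-linked and muscle lists. Within the sets of high and low background all 110 called genes kept their direction, with 37 raised and 1 lowered gene in the former and 62 and 0 in the latter, where 157 named genes reached an unadjusted p under 0.05 downwards. The 4 decreases depended on single arrays and on the scaling. Leaving out array 4, 9, 10 or 11 left 2, 2, 2 and 1. Median scaling left 0 called by limma, against 278 at an unadjusted p under 0.05. By chance alone a share of 0.05 of the 8273 named genes, over both directions, would reach that p.

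**Figure D1:**
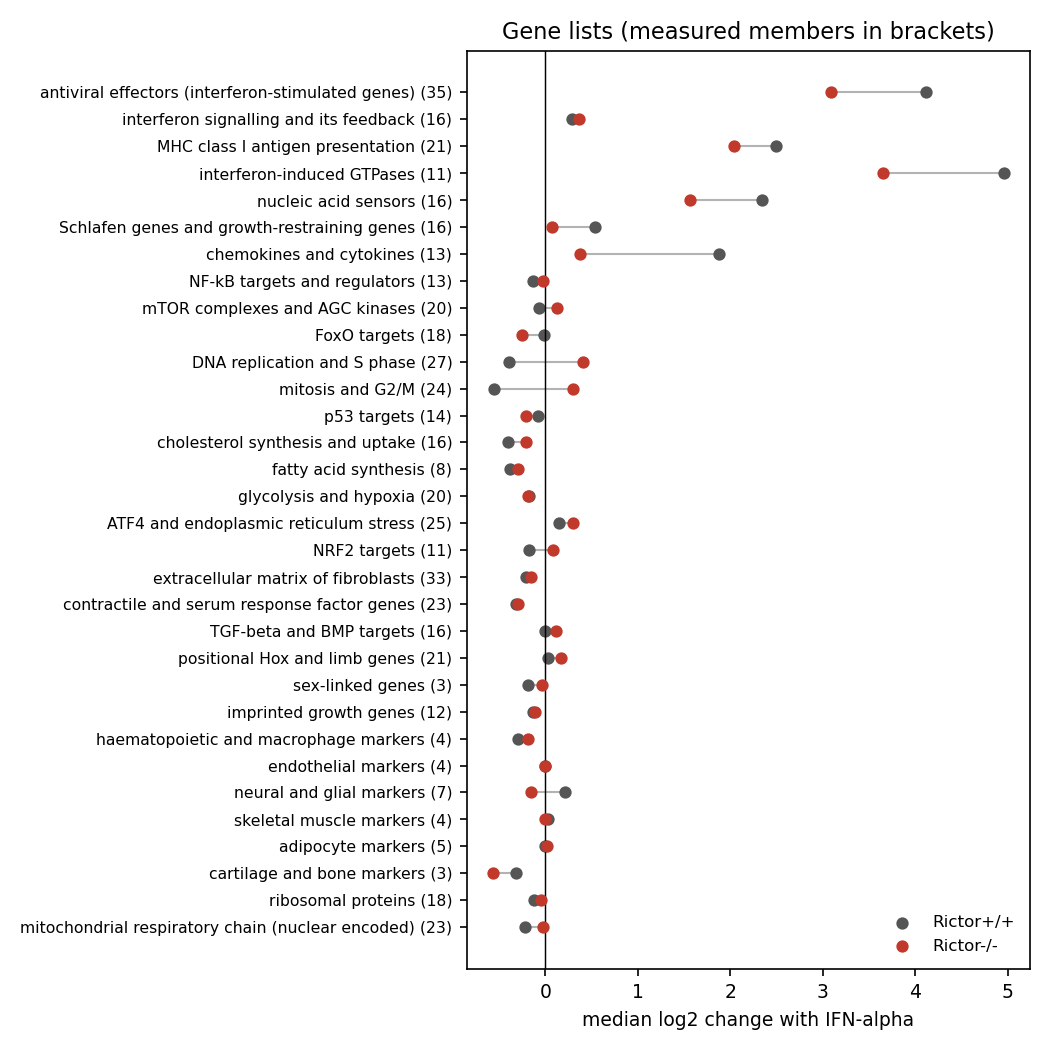
Median log2 change with IFN-alpha (x axis) over the measured members of each gene list (y axis, members in brackets) in Rictor+/+ (grey) and Rictor-/- cells (red). The 7 interferon-related lists at the top lie to the right of 0 in both lines, with antiviral effectors at 4.11 and 3.09, while mitosis genes lie at -0.56 and 0.30.

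The responses overlapped in their increases. Of the 294 and 106 raised genes 101 were shared, where 3.77 would be shared if the calls were independent, and 5 were called in Rictor-/- cells alone. Of the 294, 256 had a change of the same sign in Rictor-/- cells. Of the 42 genes lowered in Rictor+/+ cells 0 were called in Rictor-/- cells as well, where 4 were called in all, but 36 of the 42 had a change of the same sign there. Whether a response differs between the lines was read only from the test of the difference of the responses, which called 55 named genes with a smaller and 3 with a larger response in Rictor-/- cells, or 127 and 16 with array weights. All 55 were raised in Rictor+/+ cells, and 14 of them were also raised in Rictor-/- cells. Before treatment 32 of the 55 were below background on all arrays of both lines. In IFN-treated Rictor-/- cells 16 of them were above background on all 3 arrays. In the comparison with IFN-treated Rictor+/+ cells 53 were lower, whereas 7 were lower without treatment. That contrast follows in part from how the 55 were chosen, and genes below background before treatment could hardly be found lower there.

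Among the called genes with the largest fitted differences were Phf11a (limma adjusted p = 4.64e-05), Sp100, which encodes a nuclear body protein (adjusted p = 3.83e-05), Csprs, Gm4951, Mpeg1, Oasl1, Mx1, Oas1g, Xdh and Oas2. All of these but Oas1g had at least 1 group below background on all 3 arrays, so that the background sets their fitted difference and no size is given for them here. Phf11a and Oasl1 were above background in IFN-treated Rictor+/+ cells alone. Oas1g, above background on 1 of 3 untreated Rictor+/+ arrays, illustrates a response that was kept in part. Its mean log2 intensity went from 6.48 ± 0.23 (SD, n = 3) to 14.46 ± 0.32 in Rictor+/+ and from 6.78 ± 0.23 to 10.29 ± 0.14 in Rictor-/- cells. Ifit2 went from 10.14 ± 0.37 to 14.09 ± 0.42 and from 10.16 ± 0.27 to 11.04 ± 0.50, a difference of -3.07 ± 0.43 (adjusted p = 0.0045). Slfn2, which restrains proliferation in haematopoietic cells, was above background in IFN-treated Rictor+/+ cells alone (adjusted p = 0.000134). Larger responses in Rictor-/- cells were called for Ifitm3 (limma adjusted p = 0.00616), Ifi27 (2.78 ± 0.37) and Trim25 (limma adjusted p = 0.000638). The Ifitm3 signal lay near the highest of the array on 2 of 3 IFN-treated Rictor+/+ arrays, and Trim25 was below background on all 6 Rictor+/+ arrays. Ifitm3 and Ifi27 had lower signals in untreated Rictor-/- than in untreated Rictor+/+ cells. No difference was called for Usp18 (-0.65 ± 0.52), Irf9 (0.04 ± 0.47), Irf7 (adjusted p = 0.969), Stat2 (-0.76 ± 0.46), Isg15 (1.43 ± 0.36, adjusted p = 0.23), Cxcl10 (adjusted p = 0.524) or Socs1 (adjusted p = 0.469).

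**Figure D2:**
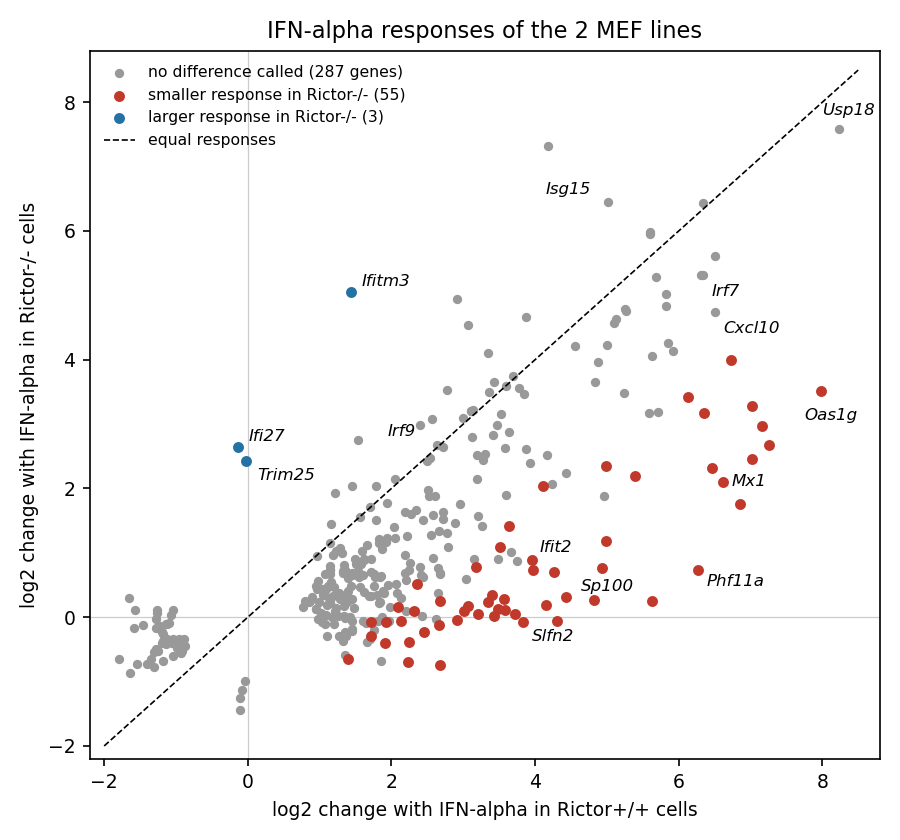
Log2 change with IFN-alpha in Rictor+/+ (x axis) against Rictor-/- cells (y axis) for the named genes called in either response or in their difference, with the line of equal responses dashed. Red points are the 55 genes with a smaller response in Rictor-/- cells, blue points the 3 with a larger response; Usp18 and Irf9 lie near the line and Phf11a and Slfn2, below background in Rictor-/- cells, at 0.74 and -0.08 on the y axis.

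Among the antiviral effectors 9 of 35 responded less and 3 more in Rictor-/- cells, or 13 and 6 when adjusted over the list alone. Their median difference was -0.53, or -0.805 with the deposited values (camera adjusted p = 7.54e-07, or 0.306 with an estimated correlation). The 9 included Oas1g, Sp100, Oas1a and Oasl1, and the 3 were Ifitm3, Ifi27 and Trim25. Chemokines and cytokines had a median difference of -1.27, or -0.464 with the deposited values (1.13e-11; 0.0101 with an estimated correlation), with Cxcl11 (adjusted p = 0.000289) and Il6 (adjusted p = 0.0115) called, both below background in Rictor-/- cells, or 8 of 13 when adjusted over the list alone. Schlafen and growth-restraining genes had -0.52, or -0.784 with median scaling (8.42e-07; 0.0311 with an estimated correlation), with Slfn2 and Casp1 called, or 6 of 16 when adjusted over the list alone. Casp1, which was below background outside IFN-treated Rictor+/+ cells, was called in 11 of 30 alternatives, with adjusted p from 0.00768 to 0.933, and the list median was -0.295 without array 12. Nucleic acid sensors had -0.54, or -0.867 with median scaling (2.21e-05; 0.0311 with an estimated correlation), with Ifi205 (adjusted p = 0.00254) and Zbp1 (-2.43 ± 0.46) called, or 5 of 16 when adjusted over the list alone; Zbp1 was called in 15 of 30 alternatives. For MHC class I genes the median was -0.76 (3.03e-10; 0.0607 with an estimated correlation), with Psmb9 (-3.19 ± 0.40) and the class I heavy chain H2-D1 (-2.64 ± 0.51, adjusted p = 0.0499) called, or 10 of 21 when adjusted over the list alone; H2-D1 was called in 16 of 30 alternatives. The GTPases had a median of -0.49 with 0 of 11 called by limma, or 1 when adjusted over the list alone (0.000951; 0.155 with an estimated correlation). Their median was -1.16 within the arrays of high background and 0.13 within those of low background, so that it changed sign between the sets, and -0.807 without array 11. The interferon signalling list was not called (0.351), with 0 of 16 members called by limma. Under median scaling the median of all features was -0.268 against -0.00346. The Schlafen and sensor medians given for that setting therefore include a general shift.

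The growth-related lists moved the other way in this test. Mitosis genes had a median difference of 0.99 (camera adjusted p = 1.09e-12; adjusted p = 0.243 with an estimated correlation), and 0.60 was the value for DNA replication genes (1.41e-08; 0.366 with an estimated correlation). In the arrays of high and low background these medians were 1.63 and 0.406 for mitosis and 1.21 and 0.404 for DNA replication, for which it was 0.306 without array 3 and 0.289 with median scaling. The respiratory chain had a median difference of 0.16 (0.0139; 0.366 with an estimated correlation), which became -0.15 with median scaling, a setting under which the median of all features was -0.268 against -0.00346; without array 10 the respiratory median was 0.108, and in the arrays of high background 0.363. No member of the 3 lists was called by limma, also when adjusted over the list alone, and Birc5 (survivin) had a difference of 1.29 ± 0.42 and Rrm2 1.56 ± 0.46. The other 22 tested lists were not called, with adjusted p from 0.0618 to 0.954; the median, mean and test differed in sign for the NF-kB, glycolysis, NRF2, TGF-beta and imprinted lists. Within the arrays of high and of low background all 58 genes kept their direction and reached an unadjusted p under 0.05, but 0 were called by limma in either set. There the 6 arrays of a set left each comparison with 1 or 2 arrays per group.

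**Figure D3:**
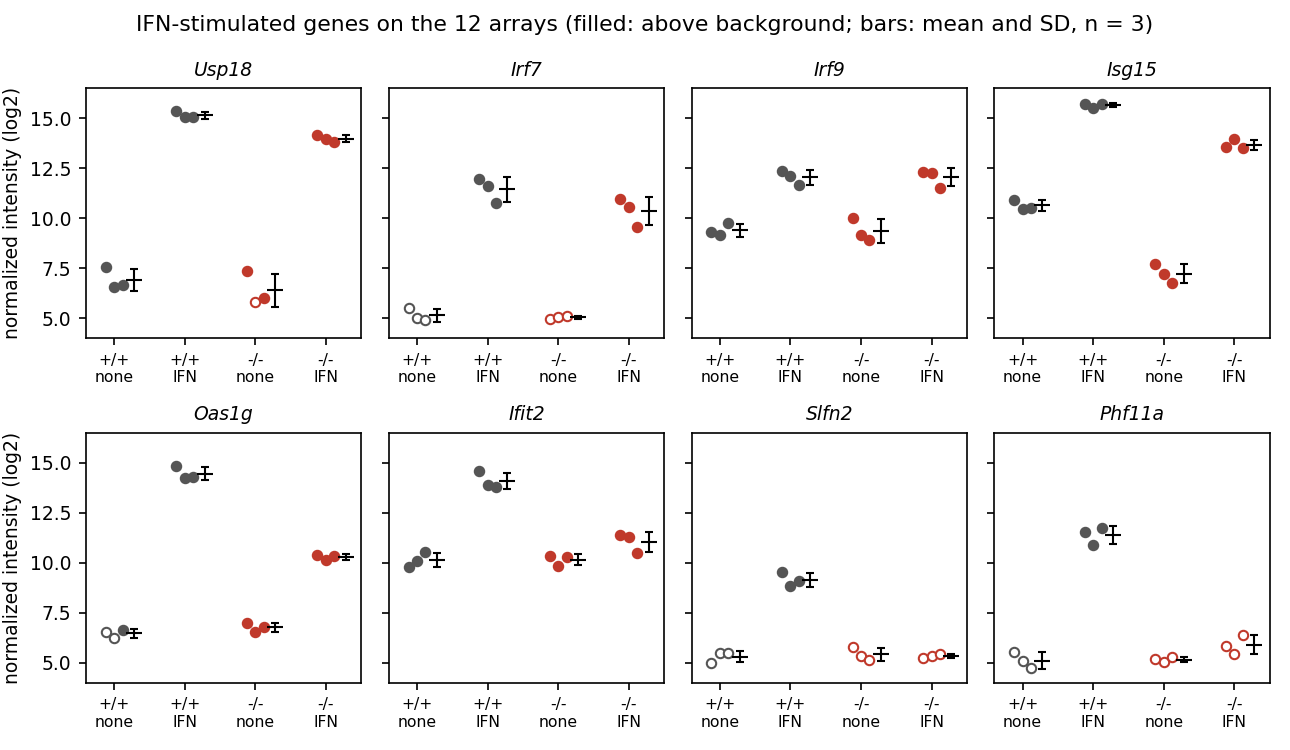
Normalized log2 intensity (y axis) of 8 interferon-stimulated genes on each array, by genotype and treatment (x axis); filled circles are above background, and bars show the mean and SD of 3 arrays. Usp18, Irf7, Irf9 and Isg15 (top) rise in both lines, and Oas1g, Ifit2, Slfn2 and Phf11a (bottom) have a smaller response in Rictor-/- cells.

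The lines also differed before treatment, which is the background to every comparison above. In untreated Rictor-/- cells 877 named genes were higher and 962 lower than in untreated Rictor+/+ cells, 634 and 747 of them at least 2-fold. Among the large increases were those of Stmn2, a microtubule regulator of neurons (at least 180.5-fold, limma adjusted p = 1.22e-08), and Dkk3 (at least 86.0-fold). The transcription factor genes Tfap2b, Tfap2a and Alx4 were at least 57.7-fold, at least 48.7-fold and at least 30.1-fold higher. Large decreases were those of the transcription factor genes Zic1 (at least 94.1-fold) and Hoxb7 (at least 98.3-fold) and of Cyp1b1, a cytochrome P450 (162-fold).

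Genes that mark position in the body were lower as a group. Of 21 measured Hox and limb genes 16 were lower in Rictor-/- cells, 2 were higher and 3 were not called, also when adjusted over the list alone, with a median of -2.72, or -1.51 with the deposited values (camera adjusted p = 1.17e-08; 0.00823 with an estimated correlation). Hoxd8 and Hoxa5 were at least 21.7-fold and at least 16.7-fold lower, and Tbx3 was at least 15.8-fold higher. This was the only list called in this comparison with an estimated correlation. Of 27 DNA replication genes 14 were lower, or 19 when adjusted over the list alone, with Cdc45 4.21-fold and Mcm4 3.23-fold lower (1.18e-05; 0.676 with an estimated correlation). Of 25 ATF4 and stress genes 10 were lower, or 13 when adjusted over the list alone, led by the amino acid transporter Slc7a3, with a log2 difference of -4.52 ± 0.31 (0.000386; 0.397 with an estimated correlation). Of 33 matrix genes 15 were lower and 3 higher, or 16 and 5 when adjusted over the list alone, with Col1a2 7.63-fold and Dcn 6.96-fold lower (0.0164; 0.676 with an estimated correlation). Of 12 imprinted growth genes 8 were lower and 2 higher, or 9 and 2 when adjusted over the list alone, with Igf2, a fetal growth factor, 40.5-fold and Dlk1 8.79-fold lower (0.0164; 0.482 with an estimated correlation). Of 5 adipocyte markers 3 were lower, also when adjusted over the list alone, namely Pparg (at least 11.6-fold), Lpl (24.3-fold) and Ebf2 (0.0164; 0.397 with an estimated correlation).

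Interferon-stimulated genes were already lower in part without added IFN-alpha. Of 35 antiviral effectors 13 were lower, 2 higher and 20 not called in untreated Rictor-/- cells, or 14 and 2 when adjusted over the list alone (camera adjusted p = 0.00353; adjusted p = 0.676 with an estimated correlation). Isg15 was 10.6-fold, Ifitm3 20.6-fold and Rsad2 at least 5.81-fold lower, while Trim25 was at least 13.7-fold higher. Cxcl10 was at least 2.93-fold lower and Ccl5 was lower too (adjusted p = 2.02e-07). Ifnar2 was 1.99-fold lower (adjusted p = 0.026). Stat2 (0.46 ± 0.32), Irf9 (-0.04 ± 0.33) and Usp18 (-0.53 ± 0.37) were not called, and Irf7 was below background in both. The other 25 tested lists were not called, with adjusted p from 0.176 to 0.997; they include the mTOR list, with 2 of 20 higher and 3 lower, the FoxO list, with 3 of 18 higher and 2 lower, and the marker lists of blood, endothelial, neural, muscle and cartilage cells. In the mTOR list Sgk1 (2.38 ± 0.19) and Mtor (1.13 ± 0.19) were higher and Prr5 (-2.14 ± 0.37) and Ddit4 (-0.90 ± 0.22) lower, and in the FoxO list Pdk4 (3.14 ± 0.28) was higher and Txnip (-2.27 ± 0.45) and Bcl2l11 lower. For the MHC class I, NF-kB, mitosis, fatty acid, glycolysis and neural lists the median, mean and test differed in sign. Among the markers Cd14 was 3.95-fold and Col2a1 5.50-fold higher and Cd74 at least 4.43-fold lower. The epithelial list had 2 measured members and was not tested; Krt7 was 3.51-fold higher. Within the arrays of high and low background all 1839 called genes kept their direction, with 307 and 158 called higher and 396 and 283 called lower. Median scaling gave 415 higher and 696 lower genes, so that 37.4% of the calls were higher against 47.7%, and array weights gave 1879 and 2051.

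With IFN-alpha 946 named genes were higher and 1254 lower in Rictor-/- than in Rictor+/+ cells. The position-related and other line differences were present here too, with Hoxb7 at least 103-fold and Cyp1b1 299.9-fold lower and Stmn2 at least 114-fold higher. Trim25, an E3 ligase that acts on RIG-I, was at least 78.8-fold higher (limma adjusted p = 1.83e-10). Of the antiviral effectors 21 of 35 were lower and 1 higher, or 26 and 1 when adjusted over the list alone, with a median of -1.56 (camera adjusted p = 5.47e-10; adjusted p = 0.181 with an estimated correlation). Oas1a was at least 9.06-fold and Isg15 3.95-fold lower, and Sp100 was lower too, being above background on 1 of 3 IFN-treated Rictor-/- arrays (adjusted p = 3.33e-08). Among the chemokines and cytokines 8 of 13 were lower and 1 higher, or 8 and 2 when adjusted over the list alone (0.00158; 0.181 with an estimated correlation), with Ccl5 at least 25.5-fold and Cxcl10 14.0-fold lower. Of the MHC class I genes 9 of 21 were lower, or 12 when adjusted over the list alone (0.000473; 0.189 with an estimated correlation), with Psmb8 8.87-fold lower. Lower counts were 4 of 11 for GTPases (0.00359), 7 of 16 for nucleic acid sensors, with 1 higher (0.024), and 8 of 16 for Schlafen and growth-restraining genes (0.0024), or 9, 8 and 10 when adjusted over the list alone, and each had an adjusted p of 0.181 with an estimated correlation.

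In the same comparison 9 of 24 mitosis genes were higher in IFN-treated Rictor-/- cells, or 11 when adjusted over the list alone, with a median of 0.95 (camera adjusted p = 3.15e-05; adjusted p = 0.366 with an estimated correlation). Cenpf was 2.48-fold, Prc1 2.17-fold and Ect2 2.26-fold higher. Without IFN-alpha 1 of the 24 had been higher, Cenpf, and the list was not called (0.991), with medians of -0.672 and 0.333 in the arrays of high and low background; with IFN-alpha the median was 0.631 in the latter and 0.535 with median scaling. Of the DNA replication genes 4 of 27 were lower with IFN-alpha and the list was not called (0.283). The Hox and limb list remained low, with 15 lower and 2 higher of 21, or 16 and 3 when adjusted over the list alone (6.56e-07; 0.0199 with an estimated correlation). Calls that were lost with an estimated correlation were also made for ATF4 and stress genes (0.00359; 0.189), matrix genes (0.024; 0.366), imprinted genes (0.0124; 0.207) and adipocyte markers (0.00686; 0.181), all lower, and for cholesterol synthesis, which was higher (0.048; 0.465). The other 19 tested lists were not called, with adjusted p from 0.0732 to 0.963; the median, mean and test differed in sign for the mTOR, glycolysis and neural lists. Within the arrays of high and low background all 2200 called genes kept their direction, with 307 and 189 called higher and 499 and 359 lower. Median scaling gave 333 higher and 1341 lower genes, so that 19.9% of the calls were higher against 43.0%, with the median of all features at -0.256 against 0.0384, and array weights gave 1528 higher genes.

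**Figure D4:**
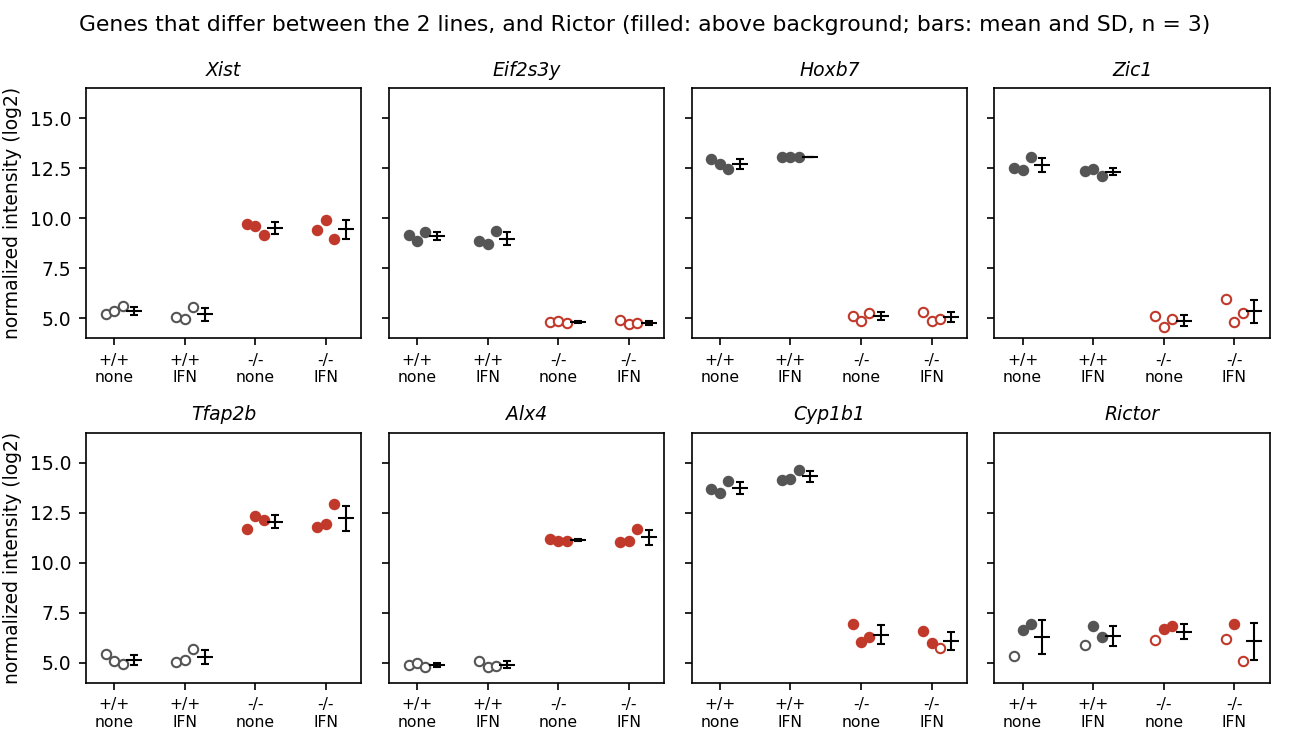
Normalized log2 intensity (y axis) of 7 genes that differed between the lines and of Rictor on each array, by genotype and treatment (x axis); filled circles are above background, and bars show the mean and SD of 3 arrays. Xist, Tfap2b and Alx4 are high in all Rictor-/- groups and Eif2s3y, Hoxb7, Zic1 and Cyp1b1 in all Rictor+/+ groups, while Rictor lies near background in all 4 groups.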

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

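The tests on other probes, on swapped arrays, on the sex of the lines and on signal ceilings were chosen after the results were seen. The results below are listed because the response to IFN-alpha differed between Rictor-/- and Rictor+/+ cells by a limma test of the difference itself.

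A smaller response in Rictor-/- cells was called for 55 named genes. The log2 differences were -5.53 for Phf11a, -5.38 for Sp100, -5.10 for Csprs, -4.59 for Gm4951, -4.57 for Mpeg1, -4.55 for Oasl1, -4.52 for Mx1, -4.46 for Oas1g, -4.36 for Xdh, -4.20 for Oas2 and -4.11 for Oas1a. They were -3.91 for Slfn2, -3.67 for Cxcl11, -3.19 for Psmb9, -3.07 for Ifit2, -2.74 for Ifi205, -2.64 for H2-D1, -2.43 for Zbp1, -1.93 for Casp1 and -1.84 for Il6. Of these, Ifit2 and H2-D1 were above background on all arrays, Zbp1 on all but 1, and Oas1g and Psmb9 on 1 of 3 untreated Rictor+/+ arrays, so that the background shapes the values of the latter in part. For the others the background sets the fitted value, which is neither a size nor a bound. A larger response was called for 3 genes, with 3.62 for Ifitm3, whose size a signal ceiling in Rictor+/+ cells may have changed (see the 89.3% below), 2.78 for Ifi27 and 2.44 for Trim25, which was below background on all Rictor+/+ arrays. Median differences were -0.53 for antiviral effectors (-0.805 with the deposited values) and -0.762 for MHC class I genes. For GTPases the value was -0.488 (-1.16 in the arrays of high and 0.127 in those of low background). Nucleic acid sensors had -0.542 (-0.867 with median scaling) and Schlafen and growth-restraining genes -0.521 (-0.295 without array 12). Chemokines and cytokines had -1.27 (-0.464 with the deposited values). The median was 0.602 for DNA replication (0.306 without array 3) and 0.164 for the respiratory chain (-0.145 with median scaling). For mitosis it was 0.993 (1.63 in the arrays of high and 0.406 in those of low background). With median scaling the median of all features was -0.268 against -0.00346, so the sensor and respiratory values under that setting include a general shift. With an estimated correlation the sensor, Schlafen and chemokine lists kept their call and the other 6 did not.

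The smaller response of the 55 genes was set against 3 technical explanations. Array 12, a dim array of the IFN-treated Rictor-/- group, is argued against as the whole cause, since 46 of the 55 were still called without it, although the Schlafen list median then lay nearer to 0. A sequence variant under single probes is argued against for the 17 genes with other kept probes, since all 24 of these probes were lower and 87.5% of them reached an unadjusted p under 0.05; for the other 38 genes there was no second probe and this stays open. A uniformly weaker response is argued against only for 40 IFN-list genes raised in Rictor+/+ cells and above background on all untreated arrays. Of these, 32.5% departed from the common slope of 0.823, which was the median ratio of the same genes. There were 7 below, such as Ifit2 with a ratio of 0.223, and 6 above, such as Isg15 with 1.29. The ratio compares log2 changes and so depends on the untreated level. Isg15 began lower in untreated Rictor-/- cells and stayed lower there with IFN-alpha, so its ratio does not stand for a higher level. Of the 55 genes only Ifit2 and H2-D1 were among the 40, so for the others a uniformly weaker response stays open. A difference in the response itself may therefore remain as a hypothesis, but genotype and cell line coincide, so the loss of Rictor and other differences between the lines stay open as its source.

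Xist and the Y-linked genes were opposite in the lines. An array swapped between the lines is argued against, because on 12 of 12 arrays every measured sex-linked gene lay on the side of the labelled line. These genes cannot show a swap of untreated and IFN-treated arrays within a line, or an exchange of the lines as a whole. Lines from embryos of different sex may account for it, since 3 of 3 measured sex-linked genes separated the lines with no overlap. The sex of the embryos is not labelled. The differences between the lines can therefore include sex as well as Rictor.

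The larger responses of Ifitm3, Ifi27 and Trim25 had different backgrounds. For Ifitm3 a signal ceiling in Rictor+/+ cells may play a part, since its signal reached 89.3% of the highest on an IFN-treated Rictor+/+ array. For Ifi27 this is argued against, with 5.78%. Its signal was 3724.3 to 4347.1 on untreated and 3160.9 to 4165.2 on IFN-treated Rictor+/+ arrays. In Rictor-/- cells it was 508.6 to 1114.9 without and 1389.5 to 5139 with IFN-alpha, so the response there began from a lower level. Untreated Ifitm3 was lower there too, at 666.7 to 2049.1 against 16828 to 22651.5. For Trim25 a sequence variant under 1 probe in Rictor+/+ cells is argued against, because the other Trim25 probe was above background on 0 of 6 Rictor+/+ and 3 of 3 IFN-treated Rictor-/- arrays. A difference between the lines apart from Rictor stays open for all 3.

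Other splits of the arrays were tried for each count. For the difference of responses 2 of 100 drawn splits of the genotype labels, out of 200, gave as many genes, the real one with 58 included. The other gave 3454, and it exchanges the genotypes among the IFN-treated arrays alone, so that it measures the difference between the lines, a structure of the samples. The next 8 gave 39 to 56 genes, and each parts the IFN-treated arrays by line and mixes the untreated arrays. A split that mixes the lines within a group also counts the line difference as residual spread. These splits therefore do not show whether chance is excluded. For the other comparisons 1 of 10 splits, the real one, gave as many genes, with 336 for IFN-alpha in Rictor+/+ and 110 in Rictor-/- cells, 1839 between the untreated and 2200 between the treated lines, and 0 as the highest other each time. These 10 splits are too few for a share under 0.05.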

How the results depend on the processing

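The saddle-point background, the offset of 50, the fits within and with the background sets, leaving out arrays 1, 10 and 12 together, the list medians without each array and the adjustment over named genes only were chosen after the data had been seen. Of the genes that the text names by rule, no called one reversed. Of all called genes, with the mean of a gene's probes 876 of 877 and 961 of 962 kept their direction between untreated lines and 945 of 946 and 1252 of 1254 between treated lines, and with the saddle-point background 1253 of 1254. For the difference of responses the median of 2 called lists changed sign. These were the GTPases within the arrays of low background (0.127 against -0.488) and the respiratory chain with median scaling (-0.145 against 0.164). With median scaling the median of all features was -0.268 against -0.00346, so the respiratory median still lay above that of all features. Causes were not tested except where fewer arrays account for a change.

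Genes lowered by IFN-alpha in Rictor+/+ cells (42) numbered 70 with no background correction, 6 with median scaling and 20 with only the 2 groups compared. Genes lowered in Rictor-/- cells (4) numbered 2 with cyclic loess, 2 with trend and robust moderation, 1 with the deposited values and 1 with the saddle-point background. They numbered 0 by limma with median scaling and 0 with only the 2 groups compared, against 278 and 244 at an unadjusted p under 0.05. Larger responses in Rictor-/- cells (3) numbered 5 with no background correction and 5 with the deposited values. Median scaling gave 415 genes higher in untreated (877) and 333 in IFN-treated Rictor-/- cells (946). For all of these the cause was not tested. Chance alone gives a share of 0.05 of the named genes, over both directions, at an unadjusted p under 0.05.

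Array weights gave 481 raised and 280 lowered genes in Rictor+/+ cells, 163 and 15 in Rictor-/- cells, 16 larger and 127 smaller responses, 1879 higher and 2051 lower genes between untreated lines and 1528 higher with IFN-alpha; the cause was not tested. Within the 6 arrays of high background, with fewer arrays, 199 were raised and 5 lowered in Rictor+/+ and 37 and 1 in Rictor-/- cells. Within the 6 of low background these were 78 and 1, and 62 and 0 by limma (157 at an unadjusted p under 0.05). Responses differing between the lines numbered 0 larger and 0 smaller by limma in both sets, against 356 and 426, and 89 and 194, at an unadjusted p under 0.05. Between untreated lines the sets gave 307 higher and 396 lower, and 158 and 283. With IFN-alpha they gave 307 and 499, and 189 and 359. All called genes kept their direction in both sets.

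With an estimated correlation the lists called lower were 0 (of 6) for IFN-alpha in Rictor+/+, 0 (of 1) in Rictor-/- cells, 3 (of 6) for the difference, 1 (of 7) between untreated and 1 (of 11) between treated lines, and those called higher were 0 (of 3) for the difference and 0 (of 2) between treated lines. In Rictor-/- cells the lists lowered by IFN-alpha were 0 with cyclic loess, 0 with the deposited values and 4 without arrays 1, 10 and 12. Lists higher between treated lines were 1 with cyclic loess and 5 with the deposited values, and 1 was higher between untreated lines (0) without arrays 1, 10 and 12. The cause was not tested.

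Leaving out each array in turn gave 225 to 321 raised and 19 to 55 lowered genes in Rictor+/+ cells, 88 to 111 and 1 to 5 in Rictor-/- cells, 3 to 4 larger and 43 to 57 smaller responses, 624 to 1026 higher and 708 to 1130 lower genes between untreated lines, and 667 to 1011 and 905 to 1317 with IFN-alpha. Genes lowered in Rictor+/+ cells numbered 19 without array 2, 20 without 5, 27 without 6 and 26 without 9. In Rictor-/- cells they numbered 2 without array 4, 2 without 9, 2 without 10 and 1 without 11.

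Without an array, medians of called lists that moved by over 1.5 times were, in Rictor+/+ cells, interferon signalling (0.533 without array 9 against 0.295), DNA replication (-0.253 without 2 against -0.394) and contractile genes (-0.0938 without 1 against -0.318). In Rictor-/- cells they were interferon signalling (0.232 without 3, 0.571 without 8 and 0.207 without 12 against 0.369), DNA replication (0.102 without 3 against 0.405) and mitosis (0.0431 without 3 and 0.201 without 12 against 0.302). For the difference they were GTPases (-0.807 without 11 against -0.488), Schlafen genes (-0.295 without 12 against -0.521), DNA replication (0.306 without 3 against 0.602) and the respiratory chain (0.108 without 10 against 0.164). Between untreated lines it was matrix genes (-0.971 without 3 against -0.594), and between treated lines none.

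With the deposited values, medians of called lists that moved by over 1.5 times included, for the difference of responses, antiviral effectors (-0.805), GTPases (-0.765) and chemokines (-0.464), and between untreated lines Hox and limb genes (-1.51). With median scaling they included, for the difference, GTPases (-0.781), sensors (-0.867) and Schlafen genes (-0.784).

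Of the 23 genes that the text names by rule and that had a called difference of responses (of 58 called), Casp1 was called in 11 of 30 alternatives, Zbp1 in 15 and H2-D1 in 16. A block on the BeadChip was not run, as no chip was given. Signal over background limits dim genes, since 32 of the 55 genes with a smaller response were below background on all untreated arrays.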
